A study of Homo sapiens with 96 samples.

How the data were processed

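The series measured gene expression by RNA sequencing in RPE-hTERT cells, a human retinal pigment epithelial line immortalised with telomerase, that carry an HA-tagged BRAF V600E transgene under doxycycline control. BRAF is a kinase at the top of the MEK and ERK cascade, and the V600E change keeps it active. SCH772984, the inhibitor used, blocks the ERK kinases at the bottom of that cascade. Per the labels' protocols, cells were grown for 48 h to about 50% confluency, received doxycycline (250 ng as written there, with no volume) with or without inhibitor, and each condition was run on a pair of different days. Stranded poly(A) libraries were made from 300 to 500 ng of RNA with 12 PCR cycles and a mean fragment of 370 bp, and were read from a single end over 114 bp. Doxycycline was given only to induced cells, so its own effect cannot be separated from that of the transgene.

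The authors deposited a table of raw counts, whole numbers of reads per gene and library, for 58735 Ensembl gene identifiers and 96 libraries. The submitters' processing notes name cutadapt 2.3, HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 and DESeq, and the build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. A second deposited table holds the authors' log2 fold changes and adjusted p-values for 19930 genes in 42 conditions. It names no reference condition; the 0 h group is the only group absent from it. A table of the authors' normalised counts was not used here. The protocol mentions synthetic spike-in RNA, but the count table holds no spike-in entries, so scaling rests on the genes themselves. All columns carried a library name found in the labels, and 0 columns were left unassigned. Gene symbols were found for 42498 identifiers.

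Libraries were grouped by the labels into 43 groups: 12 libraries at 0 h, 2 for each of the 36 groups of induced cells, and 2 for each of the 6 groups of uninduced cells at 24 h. Replicates are cultures of different days per the labels. The 12 libraries at 0 h carry only 2 replicate numbers, 6 libraries each, and the model treats them as 12 replicates, so p-values against 0 h rest partly on the spread within a number. With these libraries summed by number, induction at 8 and 24 h gave 2154 and 3000 genes, against 4668 and 4519. Total counts ran from 2537678 to 9021891 per library. The counts of the 108 pairs of libraries within groups differed by more than sampling noise, with chi-square values per degree of freedom of 1.42 to 46.3 over genes with at least 20 counts.

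Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) in R 4.3.3. The filter filterByExpr (minimum count 10, minimum total 15) kept 13103 genes. A single model of all 43 groups left 53 residual degrees of freedom, with a common biological coefficient of variation of 0.1282. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were induced cells at 1, 2, 4, 8, 16 and 24 h against 0 h, uninduced cells at 24 h against 0 h, induced against uninduced cells at 24 h with 0 and 1000 nM inhibitor, and each dose (3.9, 15.6, 62.5, 250 and 1000 nM) against 0 nM at 24 h with and without induction. Joint tests covered any dose at each earlier time and the induction by inhibitor interaction at 24 h, giving 25 counts of genes in all. Levels are CPM, counts scaled to the library total with the TMM factor, given as mean and SD. A fold against a group with 0 counts was computed against a floor of 3 counts over the group; with 1 to 3 counts, the ratio of CPM is given with an exact 95% interval. Such intervals and floors cover counting error only.

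Fixed gene lists numbered 21: immediate-early transcription factors; ERK feedback and pathway output; DNA replication and G1/S; mitosis and G2/M; CDK inhibitors; p53 targets; inflammatory cytokines and chemokines; EGFR ligands and secreted growth factors; proteases and the plasminogen system; extracellular matrix and contractile genes; receptor tyrosine kinases; retinal pigment epithelium differentiation; interferon response; ATF4 and the integrated stress response; mitochondrially encoded proteins; sterol synthesis; ribosome biogenesis; glycolysis and hypoxia; and markers of fibroblasts, keratinocytes, and leukocytes with endothelium. Of these, 20 had at least 2 measured members and were tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists), which sets a list against all other genes. Not every listed gene was measured: 2 of 10 keratinocyte markers, 6 of 10 fibroblast markers, 8 of 17 retinal pigment epithelium genes and 14 of 20 cytokines were. Camera with an estimated correlation and fry, which asks whether a list moves one way, were the alternatives. Ranges of a list's adjusted p over all settings pool camera with fry, although the tests ask different questions. Members were also counted with p-values adjusted over the list alone. Short names below stand for whole lists, so EGFR ligands there includes the other secreted growth factors.

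The samples, lists, comparisons and the rule for named genes were fixed before the data were examined. The rule allows BRAF; from each list, the 2 members of smallest adjusted p among those called, or else the most abundant member; the 4 highest and 4 lowest fold changes among called genes with at least 5 CPM in the higher group and both replicate numbers moving the same way (2 and 2 at 1, 2, 4 and 8 h); and the 8 genes of smallest interaction p. A gene named once may be followed elsewhere. Of the genes the rule allows, mostly those whose call survived leaving out any 1 library are described; exceptions are given with their values.

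Settings varied by plan were RLE scaling, no filter, a stricter filter (mean of 1 CPM), DESeq2 1.42.0, a model of the compared groups alone, the replicate number as a block, the 0 h libraries summed by replicate number, and leaving out each replicate. For the 0 h group, a replicate was the 6 libraries of a number. A group left with 1 library was assumed to vary like the others. Settings chosen after seeing the data were a correction for gene GC content and length (a loess trend of span 0.4 per library, from GENCODE release 29, covering 99.97% of tested genes, with Biostrings 2.70.1), alone and with the replicate block, and fits without the libraries of steepest GC trend. The limit for such libraries was 3 median absolute deviations (MAD) above the median slope (4 libraries), with a wider limit of 2 set after the slopes were seen (10 libraries). At 24 h the wider set held uninduced 62.5 nM replicate 1, 250 nM replicate 2 and 1000 nM replicate 1. It also held replicate 1 of induced cells with 250 and 1000 nM, and no 24 h library with 0 nM. Its other libraries were induced cells at 2, 4, 8 and 16 h, of which the 16 h library had 0 nM.

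The replicate numbers were read as days, from the treatment protocol. Over the 903 pairs of groups, the correlation of the deviations of same-numbered libraries from their group means ran from -0.6 to 0.59 (median 0.03, with 34.2% above 0.1). Among the 0 h libraries, component 2 (11.9% of the variance) separated the numbers. Over all libraries, component 2 (15.9% of the variance) ranked genes by GC content (absolute Spearman rho 0.68 across genes, which are not independent replicates) and length (0.54).

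The scripts were tested on simulated counts with 200 changed genes among 13103. Simulated genes varied independently at the dispersion trend, with no GC or length trend, replicate-number structure or correlation between genes. The false calls and list calls below therefore do not measure the error rate in the real libraries. For induction at 24 h, 49.3%, 80.6% and 92.4% of genes changed 1.5-, 2- and 4-fold were recovered, with 8 false calls. For 1000 nM inhibitor in induced cells the shares were 22.4%, 52.2% and 97% (9 false calls), and for the joint test at 2 h 17.9%, 76.1% and 90.9% (4 false calls). For the joint test the simulated genes were changed at 1000 nM alone, so its shares do not measure recovery of changes across several doses. A mitosis list lowered in the simulation was called in both comparisons tested, and so were 3 and 1 other lists, each of which held a changed gene.

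Some values are uncertain because reads could be shared. BRAF counts join the transgene and the endogenous gene. If strand was not used in counting, genes overlapping another on the opposite strand are affected. Among those named are ACTA2 with FAS and STAMBPL1, COL4A1 with COL4A2, CEMIP with MESD, BRAF with NDUFB2, CCNA2 with EXOSC9, CCND1 with LTO1, GNL3 with PBRM1, MEST with COPG2, TNFRSF10B with RHOBTB2, CRYAB with HSPB2, THBS1 with FSIP1, and IFIT1 and IFIT2 with LIPA. KRT15 and KRT18 belong to a family with near-identical copies.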

Results

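Gene expression was measured in 96 libraries of RPE-hTERT cells, a telomerase-immortalised human retinal pigment epithelial line in which doxycycline induces BRAF V600E, an activated form of the kinase that drives the MEK and ERK cascade. Induced cells were collected at 1, 2, 4, 8, 16 and 24 h with 0, 3.9, 15.6, 62.5, 250 or 1000 nM of the ERK inhibitor SCH772984, with 2 libraries in each of these 36 groups. Uninduced cells were collected at 24 h at each dose (2 libraries in each of 6 groups) and at 0 h (12 libraries). The design asks how transcription changes over time after oncogenic BRAF is switched on, and how the response depends on the dose of inhibitor with and without it. Library totals ran from 2537678 to 9021891 counts, and the shallowest library was replicate 1 of induced cells at 24 h with 1000 nM (its partner had 4504090 counts). Gene positions are those of GENCODE release 29 on GRCh38.

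BRAF (ENSG00000157764; chromosome 7, 140719327 to 140924928, reverse strand) was low in every uninduced library and high in every induced one. Its level was 27.18 ± 4.238 CPM (SD, n = 12) at 0 h and 24.86 ± 4.603 CPM (SD, n = 2) in uninduced cells at 24 h. It was 358.8 ± 3.818 CPM 1 h after induction, 622.4 ± 22.34 CPM at 2 h and 853.6 ± 61.24 CPM at 24 h (SD, n = 2 each). Across libraries the range was 19.01 to 34.54 CPM without doxycycline and 186 to 896.9 CPM with it. The log2 fold change at 24 h against 0 h was 4.97 ± 0.14 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.37e-40). At 24 h, induced cells with 62.5 and 250 nM inhibitor held 611.1 ± 62.37 and 608.8 ± 66.11 CPM (SD, n = 2 each). The log2 difference from 0 nM at 62.5 nM, -0.48, was not called. It was called in a model of the compared groups alone (-0.49) and without the libraries of GC slope over 2 MAD (-0.48). With 1000 nM inhibitor at 24 h, induced cells held 584 ± 87.96 CPM, a log2 difference from 0 nM of -0.55 ± 0.22 (edgeR adjusted p = 0.0416). The call at 1000 nM was lost without 0 nM replicate 1 (-0.47), 0 nM replicate 2 (-0.62) or 1000 nM replicate 1 (-0.42), in a model of the compared groups alone (-0.52), and without the libraries of steep GC trend, over 2 (-0.39) or 3 (-0.43) median absolute deviations.

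**Figure D1:**
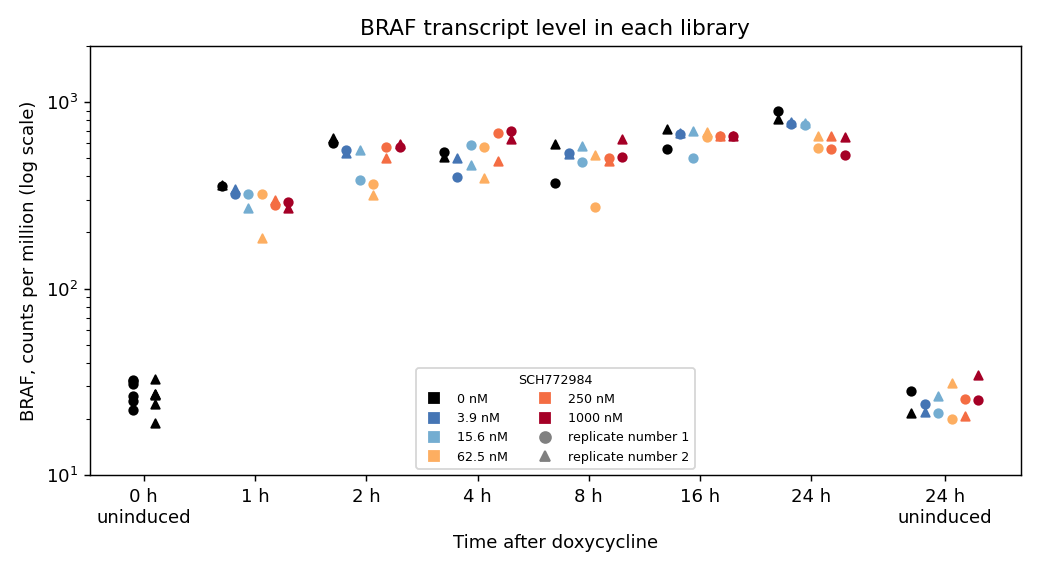
BRAF CPM (log axis) in each of the 96 libraries by hours after doxycycline, with colour for inhibitor dose and marker for replicate number. Uninduced libraries at 0 h and 24 h lie between 19.01 and 34.54 CPM, and induced libraries between 186 and 896.9 CPM.

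After 24 h of induction, inflammatory mediators and negative regulators of ERK signalling stood above their 0 h levels, and most of the extracellular matrix and contractile list below. PTGS2 (ENSG00000073756; chromosome 1, 186671791 to 186680427), which encodes the prostaglandin-producing enzyme cyclooxygenase 2, was at 650 ± 121 CPM (SD, n = 2) against 2.08 ± 0.578 CPM (n = 12), a log2 fold change of 8.27 ± 0.2 (SE; edgeR adjusted p = 1.75e-43). IL1B (ENSG00000125538; chromosome 2, 112829751 to 112836903), the cytokine interleukin 1 beta, reached 984 ± 74.2 CPM from 6.84 ± 1.4 CPM (log2 fold change 7.17 ± 0.12, edgeR adjusted p = 2.66e-51). DUSP6 (ENSG00000139318; chromosome 12, 89347232 to 89353271), a phosphatase that inactivates ERK, reached 569 ± 33.1 CPM from 16.2 ± 1.77 CPM (5.13 ± 0.1, edgeR adjusted p = 4.42e-48). BCL2A1, an inhibitor of apoptosis, had 0 counts at 0 h and was at least 264-fold higher (edgeR adjusted p = 3.08e-14).

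ANKRD1 (ENSG00000148677; chromosome 10, 90912096 to 90921276), a transcriptional target of YAP, fell to 14.2 ± 4.03 CPM from 465 ± 43.3 CPM (log2 fold change -5.03 ± 0.15, edgeR adjusted p = 6.32e-38). CEMIP (ENSG00000103888; chromosome 15, 80779343 to 80951776), which takes part in hyaluronan breakdown, fell more (-5.81 ± 0.29, edgeR adjusted p = 1.28e-26). THBS1 (ENSG00000137801; chromosome 15, 39581079 to 39599466), the matrix protein thrombospondin 1, fell to 279 ± 47.5 CPM from 3720 ± 485 CPM (-3.74 ± 0.24, edgeR adjusted p = 5.52e-21). In all, 4519 of 13103 genes passed, 2325 higher and 2194 lower, and 1393 of these differed at least 2-fold. Without replicate 2 of the induced cells the count was 2759.

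Of the 20 lists tested at 24 h against 0 h, 13 passed camera, 7 of which also passed with an estimated correlation. Among cytokines and chemokines, 12 of 14 measured members rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 2.95 (camera adjusted p = 3.96e-36). In the ERK feedback and output list, 14 of 20 rose and 1 fell (14 and 3 adjusted over the list alone, median 1.71, camera adjusted p = 4.31e-45). Members included DUSP6 and DUSP5 (log2 fold change 3.57 ± 0.11, edgeR adjusted p = 3.53e-37). Immediate-early transcription factors were higher in 14 and lower in 3 of 22 (14 and 3 adjusted over the list alone, median 1.51, camera adjusted p = 9.97e-10). Proteases and the plasminogen system were higher in 7 and lower in 2 of 10 (7 and 2 over the list alone, median 2.2, camera adjusted p = 2.19e-13), among them SERPINB2, an inhibitor of plasminogen activators (4.82 ± 0.23), and MMP14, a membrane-bound collagenase (2.06 ± 0.09). EGFR ligands and secreted growth factors were higher in 8 and lower in 4 of 15 (8 and 4 over the list alone, median 0.64, camera adjusted p = 0.000294), with BMP2 at 5.91 ± 0.17 and the angiogenic factor VEGFA at 1.53 ± 0.1. Extracellular matrix and contractile genes fell in 13 and rose in 1 of 17 (13 and 1 over the list alone, median -0.77, or -0.75 with members near 0 counts at their bound, camera adjusted p = 6.12e-08). CCN1, a matricellular protein, was among them (-3.41 ± 0.14). The keratinocyte markers KRT15 (2.02 ± 0.19) and PERP (0.77 ± 0.08), the pair measured, both rose (the same over the list alone, camera adjusted p = 0.00123). These 7 lists passed with an estimated correlation.

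The other 6 lists that passed at 24 h did not pass with an estimated correlation. DNA replication genes fell in 25 of 30 (25 adjusted over the list alone), with a median log2 fold change of -0.75 (camera adjusted p = 9.27e-10; adjusted p = 0.109 with an estimated correlation). MCM3 and MCM6, subunits of the replicative helicase, fell by 1.08 and 1 on the log2 scale. Mitosis genes fell in 14 and rose in 2 of 25 (16 and 2 over the list alone, median -0.4, camera adjusted p = 0.00266; adjusted p = 0.22 with an estimated correlation), including KIF20A, a kinesin of cytokinesis (-0.92 ± 0.1). Ribosome biogenesis genes fell in 9 of 20 (10 over the list alone, median -0.28, camera adjusted p = 0.00266; adjusted p = 0.22 with an estimated correlation), including the nucleolar protein gene NCL (-0.75 ± 0.09). Glycolysis and hypoxia genes rose in 9 and fell in 2 of 17 (9 and 2 over the list alone, median 0.34, camera adjusted p = 0.000478; adjusted p = 0.0984 with an estimated correlation), led by NDRG1 (3.67 ± 0.11). Sterol synthesis genes fell in 10 and rose in 1 of 17 (10 and 1 over the list alone, median -0.46, camera adjusted p = 0.0357; adjusted p = 0.109 with an estimated correlation). Fibroblast markers rose in 3 and fell in 1 of 6 (3 and 1 over the list alone, median 0.64, camera adjusted p = 0.0386; adjusted p = 0.0642 with an estimated correlation), including PDGFRA (2.56 ± 0.27) and PRRX1 (1.51 ± 0.11). The sterol call was lost without induced replicate 2 (0.102) or 0 h replicate 2 (0.0569), and the fibroblast call without induced replicate 1 (0.0868) or 0 h replicate 2 (0.0569). Over all settings tried, fry included, the adjusted p of these lists ran from 5.45e-09 to 0.109 and from 2.43e-15 to 0.0967. Fry asks whether a list moves one way, while camera sets a list against all other genes.

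The remaining lists did not pass camera at 24 h. CDK inhibitors were higher in 4 and lower in 3 of 7 (4 and 3 adjusted over the list alone, median 0.99, camera adjusted p = 0.126). CDKN2B, which encodes the cyclin-dependent kinase inhibitor p15, rose by 2.78 ± 0.16 (SE, log2), and CDKN1A, which encodes p21, by 1.06 ± 0.15. The CDK inhibitor list passed camera with the replicate block (adjusted p = 0.0458). It also passed fry (adjusted p = 2.01e-05), which asks whether a list moves one way and not whether it differs from other genes. Over all settings its adjusted p reached 0.332. p53 targets were higher in 3 and lower in 6 of 20 (3 and 8 over the list alone, camera adjusted p = 0.712), receptor tyrosine kinases in 4 and 6 of 13 (4 and 6 over the list alone, p = 0.308; median -0.24, mean 0.02), and interferon response genes in 3 and 6 of 14 (3 and 6 over the list alone, p = 0.273). Retinal pigment epithelium genes were higher in 1 and lower in 4 of 8 (1 and 5 over the list alone, p = 0.159), with MITF, a regulator of pigment cell identity, at -1.42 ± 0.2. ATF4 and stress response genes were higher in 4 and lower in 6 of 18 (4 and 6 over the list alone, p = 0.7). The 13 mitochondrially encoded genes passed neither singly nor as a list (p = 0.768), with MT-CO1, a subunit of cytochrome oxidase, at -0.17 ± 0.14 (edgeR adjusted p = 0.378). Of the leukocyte and endothelium markers only PECAM1, an endothelial adhesion molecule, was measured and the list was not tested; PECAM1 had 34 counts at 24 h and 12 at 0 h (log2 fold change 4.16 ± 0.55, edgeR adjusted p = 9.2e-09).

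Earlier times were compared with 0 h to follow the order of events. At 1 h, EGR1 (ENSG00000120738; chromosome 5, 138465490 to 138469315) and FOS, immediate-early transcription factors, had risen by 4.63 ± 0.16 and 4.51 ± 0.41 (SE, log2; edgeR adjusted p = 6.07e-34 and 1.99e-12). At 2 h EGR3, of the same family, stood at 6.77 ± 0.24 (edgeR adjusted p = 1.14e-30), and DUSP6 at 2.87. At 4 and 8 h ANGPTL4, a regulator of lipoprotein lipase, was higher by 4.55 ± 0.28 and 5.25 ± 0.27, and the neutrophil chemokine CXCL3 by 5.3 ± 0.44 at 8 h. BMF, which promotes apoptosis by binding BCL2 proteins, fell by 3.09 at 4 h and by 4.51 at 8 h (edgeR adjusted p = 5.73e-13 and 9.07e-15). EGR1 was at 5.51 at 2 h, at 2.52 at 8 h and at 3.47 at 24 h. IL1B climbed from 0.98 at 2 h to 4.12 at 8 h and 6.02 at 16 h. ANKRD1 was above 0 h at 2 h (0.73 ± 0.09, edgeR adjusted p = 9.66e-09) and below it at 8 h (-1.08 ± 0.11, edgeR adjusted p = 1.22e-12).

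Immediate-early genes rose in 13 of 22 at 1 h (17 adjusted over the list alone, median 1.04, camera adjusted p = 6.15e-165) and in 17 at 2 h (18 over the list alone, median 1.68, camera adjusted p = 6.46e-139). The ERK output list had 7 of 20 higher at 1 h (8 over the list alone, median 0.11, camera adjusted p = 2.34e-35) and 12 at 2 h (13 over the list alone, median 0.83, camera adjusted p = 1.22e-102). Cytokines rose in 7 of 14 at 1 h, 9 at 2 h, 11 at 4 h and 11 at 8 h (10, 10, 12 and 11 over the list alone), with medians of 1.06, 1.57, 1.9 and 2.18. All of these list calls held with an estimated correlation. EGFR ligands at 8 h were the only list called there whose median (-0.01) and mean (0.25) differed in sign (6 higher and 3 lower of 15, 6 and 5 over the list alone, camera adjusted p = 0.0119).

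The number of genes called by edgeR was 50 at 1 h (each higher), 353 at 2 h (285 and 68), 2051 at 4 h (1223 and 828), 4668 at 8 h (2541 and 2127) and 5027 at 16 h (2746 and 2281). Leaving out induced replicate 1 or 2 gave 186 or 166 at 2 h, 1214 or 667 at 4 h and 1938 or 2420 at 8 h; the count was 32 at 1 h without replicate 2 and 2010 at 16 h without replicate 1. With the 0 h libraries summed by replicate number, counts were 177 at 2 h, 788 at 4 h, 2154 at 8 h and 2941 at 16 h.

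**Figure D2:**
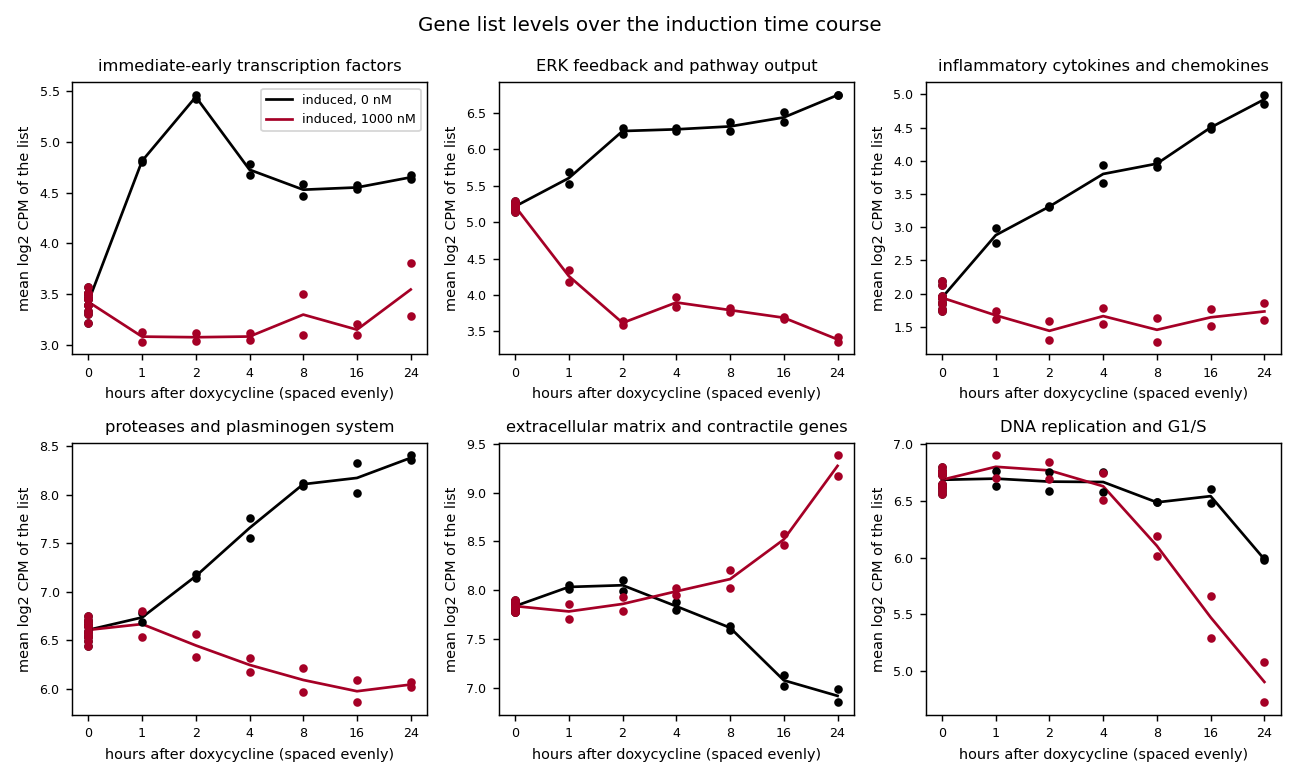
Mean log2 CPM of the members of gene lists (vertical axis) by hours after doxycycline (horizontal axis, spaced evenly) in induced cells with 0 nM (black) and 1000 nM (red) inhibitor; points are libraries and lines join group means. At 0 h both lines start from the same 12 uninduced libraries without inhibitor. Without inhibitor, cytokine and ERK output lists reach median log2 fold changes of 2.95 and 1.71 at 24 h.

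Uninduced cells at 24 h were compared with 0 h to measure culture time alone. BRAF, the cytokines and every other list gave no call: edgeR called 0 genes, with 322 at an unadjusted p under 0.05, DESeq2 called 0, and edgeR without the filter called 4. Camera called 0 of the 20 lists.

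Against uninduced cells of the same age, 24 h without inhibitor, induced cells held more cytokine and less matrix transcript. LIF, a cytokine of the interleukin 6 family, stood at 1330 CPM against 164 CPM (log2 fold change 3.03 ± 0.14, edgeR adjusted p = 6.33e-28), and PLAT, tissue plasminogen activator, was higher by 2.35 ± 0.18 (edgeR adjusted p = 3.12e-17). PTGS2 differed by 8.19 ± 0.41, IL1B by 7.18 ± 0.26 and DUSP6 by 5.23 ± 0.2. ANKRD1 was lower by 4.99 ± 0.16 (log2 -4.99), and TGFB2, a growth factor that stimulates matrix production, was at -2.8 ± 0.24. Cytokines were higher in 12 and lower in 1 of 14 (12 and 2 adjusted over the list alone, median 2.96, camera adjusted p = 4.09e-23). Matrix genes were lower in 11 and higher in 1 of 17 (12 and 1 over the list alone, median -0.77, camera adjusted p = 4.09e-10). DNA replication genes were lower in 23 of 30 (24 over the list alone, median -0.73, camera adjusted p = 1.83e-11; adjusted p = 0.0846 with an estimated correlation).

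In this comparison 2833 genes passed edgeR, 1429 higher and 1404 lower in induced cells, and 12 lists passed camera, 7 with an estimated correlation. Mitosis (adjusted p = 0.193 with an estimated correlation), ribosome biogenesis (0.21), glycolysis (0.15) and sterol synthesis (0.0846) were the other lists that did not keep their call. The sterol call was also lost without induced replicate 2 (0.0635; range 2.13e-07 to 0.0846 over all settings), and the fibroblast list (p = 0.112) passed without that library (0.0473; range 2.13e-07 to 0.196). Receptor tyrosine kinases, not called, had a median of -0.14 and a mean of 0.09.

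With 1000 nM inhibitor at 24 h, induced cells held more replication and mitosis transcripts than uninduced cells at the same dose. RRM2 (ENSG00000171848; chromosome 2, 10120698 to 10131419), which encodes the ribonucleotide reductase subunit that makes DNA precursors, was at 49.9 CPM against 4 CPM (log2 difference 3.64 ± 0.24, edgeR adjusted p = 1.47e-19). NDC80, a kinetochore component, differed by 2.82 ± 0.17 and MCM4, a helicase subunit, by 2.06 ± 0.16 (edgeR adjusted p = 4.61e-21 and 5.66e-17). Replication genes were higher in 28 of 30 (28 adjusted over the list alone, median 1.88, camera adjusted p = 2.95e-68), and mitosis genes in 24 of 25 (24 over the list alone, median 2.78, camera adjusted p = 3.16e-135). ERK output genes were higher in 10 and lower in 1 of 20 (12 and 1 over the list alone, median 1.43, or 1.13 with members near 0 counts at their bound, camera adjusted p = 2.56e-13), among them CCND1, cyclin D1 (2.11 ± 0.13). Ribosome biogenesis genes were higher in 8 of 20 (10 over the list alone, median 0.48, camera adjusted p = 2.24e-06; adjusted p = 0.107 with an estimated correlation), and matrix genes lower in 5 of 17 (7 over the list alone, median -0.25, camera adjusted p = 0.0017; adjusted p = 0.107 with an estimated correlation). IGFBP5, which binds insulin-like growth factors, was lower (195 ± 52.6 against 1050 ± 214 CPM, SD, n = 2 each). Median and mean differed in sign for immediate-early genes (-0.02 and 0.23), p53 targets (0.01 and -0.01) and fibroblast markers (-0.25 and 0.16), none of them called. In all, 1021 genes passed edgeR, 670 higher and 351 lower. A model of these 2 groups alone called 97 genes, and the GC and length correction gave 1635.

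In uninduced cells, the inhibitor lowered cell cycle transcripts and raised sterol synthesis and matrix transcripts. At 1000 nM and 24 h, RRM2 fell to 4 ± 0.938 CPM from 272 ± 13.3 CPM (SD, n = 2 each; log2 fold change -6.09 ± 0.23, edgeR adjusted p = 2.15e-32), and NDC80 fell by 4.3 (-4.3 ± 0.16, edgeR adjusted p = 2.06e-32). HMGCS1 (ENSG00000112972; chromosome 5, 43289395 to 43313512), an early enzyme of cholesterol synthesis, rose to 932 CPM from 71.4 CPM (3.71 ± 0.19, edgeR adjusted p = 3.49e-26). ACTA2 (ENSG00000107796; chromosome 10, 88935074 to 88991339), smooth muscle actin, rose to 1290 ± 293 CPM from 23.4 CPM (5.78 ± 0.25, edgeR adjusted p = 3.46e-29). SPRY4, a feedback inhibitor of the pathway, was at 0 counts and at least 38.7-fold lower (edgeR adjusted p = 3.24e-14). CHI3L1, a secreted glycoprotein, rose by 7.2 ± 0.64, and CRYAB, a small heat shock protein, by 6.22 ± 0.47.

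Replication genes fell in 30 of 30 (median -3.78, camera adjusted p = 1.11e-62) and mitosis genes in 25 of 25 (median -4.19, camera adjusted p = 1.75e-68), with the same numbers adjusted over the list alone. ERK output genes fell in 16 and rose in 1 of 20 (16 and 1 over the list alone, median -3.4, camera adjusted p = 1.89e-20), including CCND1 (-3.38 ± 0.14) and PHLDA1 (-3.9 ± 0.16). Sterol synthesis genes rose in 17 of 17 (17 over the list alone, median 1.9, camera adjusted p = 1.2e-22), matrix genes rose in 13 and fell in 1 of 17 (13 and 1 over the list alone, median 1.44, camera adjusted p = 4.04e-12), and ribosome biogenesis genes fell in 18 of 20 (18 over the list alone, median -1.29, camera adjusted p = 3.86e-10). These were the 6 lists called, and all held with an estimated correlation. Of those not called, immediate-early genes (median 0.12, mean -0.4), CDK inhibitors (0.13 and -0.33), receptor tyrosine kinases (-0.13 and 0.02) and ATF4 genes (-0.05 and 0.26) had a median and mean of opposite sign. BRAF differed by 0.26 ± 0.26 (edgeR adjusted p = 0.443). Of 5768 genes past edgeR, 2951 were higher and 2817 lower.

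At lower doses fewer genes changed in uninduced cells. At 62.5 nM, EGR1 fell by 4.6 (-4.6 ± 0.56, edgeR adjusted p = 9.23e-09) and ACTA2 rose to 210 CPM (3.16 ± 0.23, edgeR adjusted p = 3.8e-16). Sterol synthesis genes rose in 13 of 17 (15 adjusted over the list alone, median 0.71, camera adjusted p = 8.28e-23), matrix genes in 10 of 17 (11 over the list alone, median 0.7, camera adjusted p = 1.36e-24), and ERK output genes fell in 9 and rose in 1 of 20 (10 and 1 over the list alone, median -0.62, camera adjusted p = 2.88e-13). Replication genes fell in 5 of 30 (6 over the list alone, median -0.32, camera adjusted p = 3.51e-08; adjusted p = 0.28 with an estimated correlation), mitosis genes in 3 of 25 (9 over the list alone, median -0.35; adjusted p = 0.0787 with an estimated correlation) and ribosome biogenesis genes in 6 of 20 (7 over the list alone, adjusted p = 0.239 with an estimated correlation). At 250 nM the medians were -1.98 for both cell cycle lists (30 of 30 and 24 of 25 lower, the same over the list alone), 1.44 for sterol synthesis and 1.33 for the matrix.

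The counts in uninduced cells were 4806 at 250 nM (2530 higher, 2276 lower), 880 at 62.5 nM (566 and 314), 14 at 15.6 nM (9 and 5) and 15 at 3.9 nM (each higher), all by edgeR. The 15 genes at 3.9 nM were histone genes and other RNAs without poly(A) tails, high in replicate 2 of that group. In that library, small nuclear, nucleolar and Cajal body RNAs, miscellaneous RNAs and mitochondrial ribosomal RNAs made up 1.25% of counts. The median over 96 libraries was 0.134%, and this share leaves out histone genes. The share was next highest in the uninduced libraries with 1000 nM (0.275% and 0.307%), and was 0.217% and 0.243% in those with 250 nM, 0.21% and 0.24% in induced cells at 24 h with 1000 nM, 0.211% and 0.216% in induced cells at 2 h with 62.5 nM, and 0.215% in replicate 1 of induced cells at 2 h with 0 nM. Without 3.9 nM replicate 2 none of them passed. The count was 29 without 3.9 nM replicate 1, and 3 or 2 without 0 nM replicate 1 or 2. At 15.6 nM leaving out 0 nM replicate 1 or 2 gave 2 and 2, leaving out 15.6 nM replicate 1 or 2 gave 4 and 4, and the replicate block gave 26. At 62.5 nM the counts were 329 and 571 without 0 nM replicates 1 and 2, and 486 and 1326 without 62.5 nM replicates 1 and 2; a model of these groups alone called 9, ACTA2 and EGR1 among them. At 250 nM the count was 3148 without 250 nM replicate 2.

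In induced cells at 24 h, 62.5 nM inhibitor lowered cytokine and ERK output transcripts and raised replication transcripts. PTGS2 fell by 7.97 on the log2 scale (-7.97 ± 0.4, edgeR adjusted p = 3.34e-25), IL1B by 5.54 (-5.54 ± 0.23, edgeR adjusted p = 3.61e-29) and DUSP6 to 31 CPM from 569 CPM (-4.2 ± 0.18, edgeR adjusted p = 4.1e-28). ANKRD1 rose to 220 CPM from 14.2 CPM (3.95 ± 0.16, edgeR adjusted p = 1.16e-29). MCM3 rose to 309 CPM from 144 CPM (1.11 ± 0.12), and E2F2, a transcription factor of S phase genes, by 2.06 ± 0.27. CDKN2B fell by 2.94 (-2.94 ± 0.26, edgeR adjusted p = 2.73e-14).

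At 62.5 nM, cytokines fell in 11 of 14 (12 adjusted over the list alone, median -3.17, camera adjusted p = 5.51e-31), ERK output genes fell in 12 and rose in 2 of 20 (13 and 4 over the list alone, median -1.32, camera adjusted p = 9.53e-24), and replication genes rose in 24 of 30 (26 over the list alone, median 0.89, camera adjusted p = 1.18e-18). Ribosome biogenesis genes rose in 11 of 20 (13 over the list alone, median 0.55, camera adjusted p = 1.81e-07), including NOP56, a small nucleolar ribonucleoprotein component (0.81 ± 0.11). Mitosis genes rose in 8 of 25 (8 over the list alone, median 0.3, camera adjusted p = 0.000482; adjusted p = 0.145 with an estimated correlation). This last list was the only one of 11 called that did not hold with an estimated correlation. The ATF4 list (p = 0.0829) passed with the replicate block (0.044) and without 62.5 nM replicate 1 (0.0482; range 0.0109 to 0.381), and glycolysis (p = 0.0536) without 0 nM replicate 1 (0.00768; range 0.0036 to 0.321).

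At 1000 nM in induced cells cytokine and cell cycle genes fell, and sterol and matrix genes rose. IL1B was at 1.69 CPM against 984 CPM (log2 fold change -8.98 ± 0.31, edgeR adjusted p = 4.48e-34) and DUSP6 at 1.98 CPM (-8.39 ± 0.27, edgeR adjusted p = 1.33e-35). EGR1 had 2 counts, a ratio of 496 (95% interval 137 to 4100). CEMIP rose to 1490 ± 52.3 CPM from 2.09 CPM (9.46 ± 0.31, edgeR adjusted p = 3.58e-35), and HMGCS1 to 739 ± 183 CPM from 41.9 CPM (4.14 ± 0.19, edgeR adjusted p = 1.13e-27). RRM2 fell to 49.9 CPM from 260 CPM (-2.38 ± 0.17, edgeR adjusted p = 1.51e-18).

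ERK output genes fell in 17 of 20 at 1000 nM (17 adjusted over the list alone, median -2.73, camera adjusted p = 1.79e-42). Cytokines fell in 11 and rose in 2 of 14 (11 and 2 over the list alone, median -4.45, or -3.16 with members near 0 counts at their bound, camera adjusted p = 9.34e-11). Sterol synthesis genes rose in 17 of 17 (17 over the list alone, median 2.31, camera adjusted p = 2.06e-32), matrix genes rose in 15 and fell in 2 of 17 (15 and 2 over the list alone, median 2.25, camera adjusted p = 1.05e-25), and mitosis genes fell in 24 of 25 (24 over the list alone, median -1.15, camera adjusted p = 1.17e-10). Proteases fell in 8 and rose in 2 of 10 (8 and 2 over the list alone, median -2.46, camera adjusted p = 3.18e-07). Replication genes fell in 28 of 30 (29 over the list alone, median -0.99, camera adjusted p = 4.26e-10; adjusted p = 0.104 with an estimated correlation). Of 13 lists called, 6 held with an estimated correlation.

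The other lists called at 1000 nM in induced cells were close to the threshold. Immediate-early genes had 6 higher and 8 lower of 22 (6 and 9 adjusted over the list alone, camera adjusted p = 0.0147; adjusted p = 0.17 with an estimated correlation), EGFR ligands 2 and 8 of 15 (2 and 8 over the list alone, camera adjusted p = 0.0455; adjusted p = 0.0922 with an estimated correlation), and ribosome biogenesis 0 and 8 of 20 (0 and 8 over the list alone, camera adjusted p = 0.0392; adjusted p = 0.374 with an estimated correlation). Interferon genes had 5 higher and 1 lower of 14 (6 and 1 over the list alone, camera adjusted p = 0.0455; adjusted p = 0.064 with an estimated correlation), glycolysis 2 and 5 of 17 (2 and 6 over the list alone, camera adjusted p = 0.0455; adjusted p = 0.314 with an estimated correlation) and keratinocyte markers 0 and 2 of 2 (0 and 2 over the list alone, camera adjusted p = 0.0455; adjusted p = 0.0793 with an estimated correlation). With the replicate block the interferon (0.0554), glycolysis (0.0572) and keratinocyte (0.0554) calls were lost. Without 1000 nM replicate 2 only 8 lists passed: immediate-early (0.138), EGFR ligands (0.124), ribosome (0.138), interferon (0.13), glycolysis (0.239) and keratinocyte (0.0504) lists were lost and ATF4 (0.0385) was gained. Without 1000 nM replicate 1, EGFR ligands (0.106) and keratinocyte markers (0.0965) were lost. Without 0 nM replicate 2, glycolysis (0.0769), interferon (0.0661) and keratinocyte markers (0.0769) were lost and fibroblast markers (0.0379) gained. The ATF4 list (p = 0.186) had a median of -0.08 and a mean of 0.41. The ranges that follow pool camera with fry, which asks whether a list moves one way. Over all settings these p ran from 9.77e-08 to 0.17 for immediate-early genes, 1.16e-10 to 0.153 for EGFR ligands, 6.2e-05 to 0.374 for ribosome biogenesis, 2.44e-12 to 0.13 for interferon, 9.74e-06 to 0.314 for glycolysis and 1.04e-13 to 0.155 for keratinocyte markers.

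By edgeR, 259 genes changed at 3.9 nM in induced cells (103 higher, 156 lower), 965 at 15.6 nM (447 and 518), 2590 at 62.5 nM (1208 and 1382), 3340 at 250 nM (1666 and 1674) and 4809 at 1000 nM (2339 and 2470). At 3.9 nM, cytokines already fell in 8 of 14 (9 adjusted over the list alone, median -1.26, camera adjusted p = 1.58e-19) and replication genes rose in 8 of 30 (18 over the list alone, median 0.46, camera adjusted p = 8.7e-19). The counts at 3.9 nM were 63 and 165 without 0 nM replicates 1 and 2 and 82 and 96 without 3.9 nM replicates 1 and 2. At 15.6 nM they were 495 and 606, and 501 and 496, in the same order. At 62.5 nM they were 1456 without 0 nM replicate 1 and 1642 and 1701 without 62.5 nM replicates 1 and 2. At 250 nM they were 2172 without 0 nM replicate 1 and 2166 without 250 nM replicate 1.

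At the earlier times, induced cells with inhibitor were compared with induced cells without it. With 1000 nM, EGR1 was lower by 9.43 ± 0.44 at 1 h (log2 -9.43; edgeR adjusted p = 4.47e-26), and DUSP6 was at -7.96 ± 0.31 at 2 h (edgeR adjusted p = 4.94e-31). ERK output genes fell in 9 of 20 at 1 h and 15 at 2 h (11 and 17 adjusted over the list alone, medians -0.72 and -2.33, camera adjusted p = 1.35e-91 and 3.15e-163). Sterol synthesis genes rose in 13 of 17 at 4 h and in 17 at 8 and 16 h (14, 17 and 17 over the list alone, medians 0.95, 1.77 and 2.3). All of these lists held with an estimated correlation.

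The joint test over doses called 80 genes at 1 h, 3223 at 2 h, 1312 at 4 h, 2894 at 8 h and 4443 at 16 h (edgeR). At 2 h, 5698 genes differed from 0 nM at 62.5 nM, against 466 at 1000 nM. The slope of log2 CPM, relative to the mean of all libraries, on gene GC content was 0.259 and 0.225 per 10 points of GC in the 62.5 nM libraries at 2 h, -0.153 and -0.194 in the 0 nM libraries that all doses share as reference, and -0.159 to 0.131 in those of the other 4 doses. The joint count at 2 h was 429 over the other 4 doses. Leaving out induced replicate 1 or 2 of every dose gave 401 or 642 at 2 h, 700 or 477 at 4 h and 2635 or 2492 at 16 h; it gave 29 at 1 h without replicate 2 and 1286 at 8 h without replicate 1.

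The interaction asks whether the log2 change with inhibitor differed between induced and uninduced cells at 24 h. An induction difference that the inhibitor removes counts as interaction too. PLK2 (ENSG00000145632; chromosome 5, 58453982 to 58460260), a kinase of centriole duplication, rose with 1000 nM by 4.16 in induced cells and differed by 0.33 in uninduced cells, a log2 difference of 3.83 ± 0.13 (edgeR joint adjusted p over doses = 4.4e-38). NDRG1, a gene raised by hypoxia, had log2 fold changes of -3.4 in induced and 1.13 in uninduced cells at 250 nM (difference -4.53 ± 0.27; edgeR adjusted p = 3.01e-25), and BHLHE40, a repressor in the circadian clock, of -2.76 and 1.69 (edgeR adjusted p = 6.33e-30). LMNB1, which encodes the nuclear lamina protein lamin B1, had 0.99 and -2.06 at 250 nM (difference 3.05 ± 0.18; edgeR adjusted p = 1.91e-25), and KIF18B, a mitotic kinesin, 0.39 and -2.1 (2.49 ± 0.19; edgeR adjusted p = 3.24e-25).

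In all, 3218 genes passed the joint interaction test of edgeR. By dose, 23 passed at 3.9 nM, 334 at 15.6 nM, 1833 at 62.5 nM, 3637 at 250 nM and 2403 at 1000 nM. At 250 nM, replication genes were more positive in induced cells in 29 of 30 (29 adjusted over the list alone, median difference 2.71, camera adjusted p = 1.09e-60) and mitosis genes in 24 of 25 (25 over the list alone, median 2.32, camera adjusted p = 1.06e-42), and cytokines more negative in 8 and more positive in 1 of 14 (8 and 1 over the list alone, median -3.29, camera adjusted p = 5.63e-08). Sterol synthesis genes had a median difference of -0.01 (1 and 2 of 17 past the test, the same over the list alone, camera adjusted p = 0.796). A model of the 24 h groups alone called 1770 genes.

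**Figure D3:**
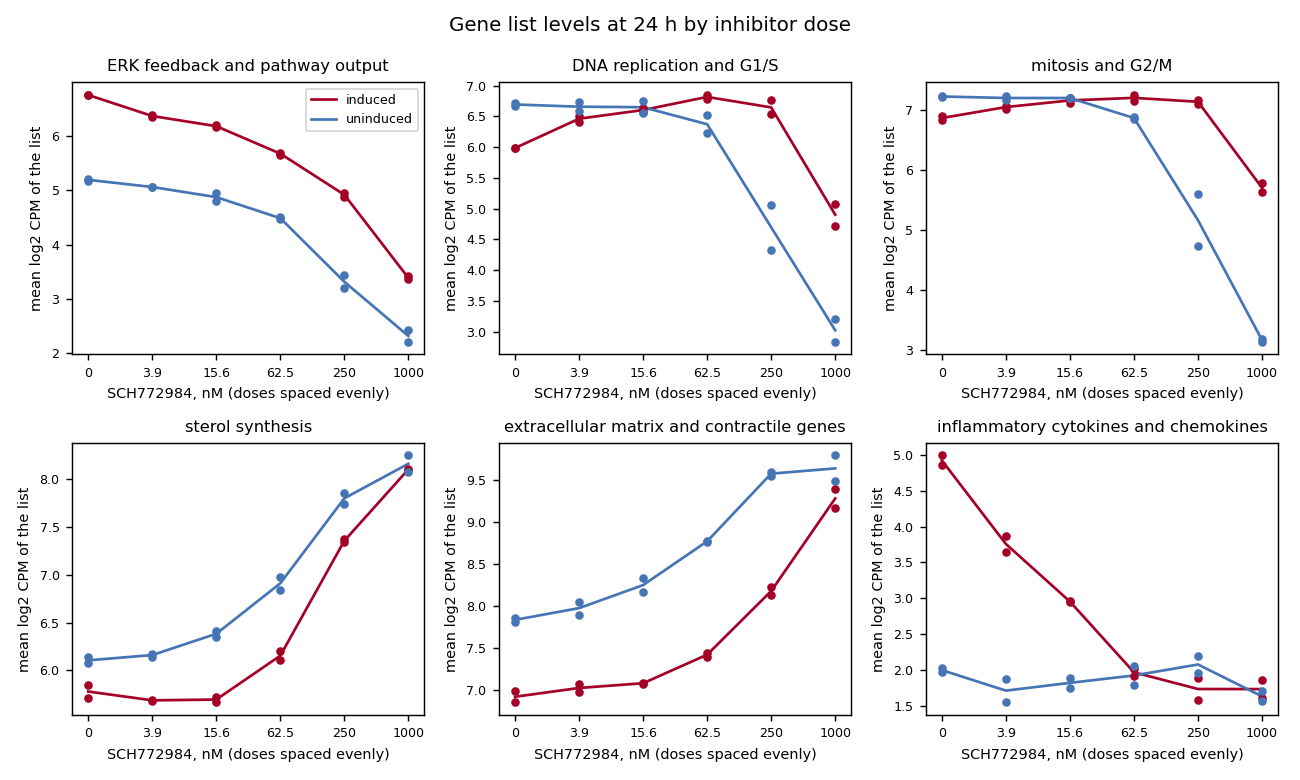
Mean log2 CPM of the members of gene lists (vertical axis) at 24 h by inhibitor dose in nM (horizontal axis, spaced evenly) in induced (red) and uninduced (blue) cells; points are libraries and lines join group means. Replication and mitosis genes stand lower in uninduced than in induced cells at 250 and 1000 nM.

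The authors' deposited table, read against 0 h, gives 68 genes under an adjusted p of 0.05 at 1 h, 403 at 2 h, 2336 at 4 h, 4737 at 8 h, 5060 at 16 h and 4432 at 24 h. Of these, 50, 334, 1942, 4386, 4668 and 4208 were also called here by edgeR. In the authors' deposited table the log2 fold change of BRAF is 3.7 at 1 h, 4.51 at 2 h and 4.96 at 24 h. For uninduced cells at 24 h the authors' deposited table gives 0 genes.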

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

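The tests of ERK output were chosen after the result was seen, as was the GC and length correction. The joint interaction test of genes was planned. Interactions by dose, and the list tests on them, were run as description and were not planned as main results.

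The inhibitor response at 24 h differed between induced and uninduced cells for 3218 genes (edgeR joint interaction over 5 doses, Benjamini-Hochberg adjusted p under 0.05) and, at 250 nM, for 9 gene lists by camera. Beside the replication, mitosis and cytokine lists, EGFR ligands and secreted growth factors (median interaction -1.29, camera adjusted p = 0.00159) and ribosome biogenesis (1.01, 6.5e-09) passed and held with an estimated correlation. So did keratinocyte markers (-1.62, 0.0202), of which only KRT15 and PERP were measured. Immediate-early genes (median -1.01, camera adjusted p = 0.00228; adjusted p = 0.131 with an estimated correlation), proteases (-1.37, 0.00826; adjusted p = 0.261 with an estimated correlation) and glycolysis (-0.24, 0.0151; adjusted p = 0.298 with an estimated correlation) did not hold. In all 9 lists the median interaction had the opposite sign to the median induction difference at 0 nM. For cytokines these were -3.29 and 2.96, for EGFR ligands -1.29 and 0.9, and for keratinocyte markers -1.62 and 1.35. The interaction subtracts the induction difference at 0 nM, so opposite signs are favoured by how it is computed. Part of the interaction can be a loss of the induction difference with inhibitor, but the signs alone do not show it. The interaction was the larger in size for cytokines, EGFR ligands and keratinocyte markers. It was also the larger for replication (2.71 and -0.73), mitosis (2.32 and -0.42), ribosome biogenesis (1.01 and -0.27) and glycolysis (-0.24 and 0.2). For immediate-early genes (-1.01 and 1.61) and proteases (-1.37 and 2.15) the interaction was the smaller.

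The 8 genes of smallest joint interaction p were PLK2 (edgeR adjusted p = 4.4e-38), ANKRD1 (1.41e-30), BHLHE40 (6.33e-30), MEST (2.33e-26), LMNB1 (1.91e-25), SPAG5 (2.58e-25), NDRG1 (3.01e-25) and KIF18B (3.24e-25). ANKRD1 had log2 fold changes at 1000 nM of 6.1 in induced and 1.01 in uninduced cells. MEST, an imprinted gene of the mesoderm, had 5.39 and 1.4. SPAG5, a mitotic spindle protein, had 0.23 and -1.89 at 250 nM.

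Induced cells kept replication and mitosis transcripts at 250 nM where uninduced cells lost them, with a median interaction of 2.49 over the 55 members of both lists. With the GC and length correction and the replicate block the median was 2.44, and both lists passed camera, which argues against a GC or length trend as the whole cause. An effect of doxycycline that changes with inhibitor dose stays open, since doxycycline was given to induced cells only. That these transcripts rise and fall with ERK output over all doses is argued against within induced cells: from 0 to 62.5 nM the mean of the ERK output list fell from 6.75 to 5.67 log2 CPM while the mean of the replication and mitosis members rose by 0.61 (6.38 to 6.99, replicates 0.61 and 0.6). Whether they follow ERK output at its lower levels cannot be told apart from other causes: at 250 nM the induced level lay -0.03 log2 from the level that uninduced cells showed at the same ERK output, but the uninduced curve is flat there (6.9 at 3.9 and 15.6 nM). At 1000 nM the induced level, 5.26, lay 0.25 above the reading of 5.01 from that curve (replicates 0.13 and 0.38), against 3.09 in uninduced cells at that dose. The curve is steep there (4.91 at 250 nM and 6.59 at 62.5 nM). That point is close to what following ERK output would give, but 1 dose does not separate it from other causes.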

How the results depend on the processing

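The GC and length correction and the fits without the libraries of steep GC trend or without the 62.5 nM dose were chosen after seeing the data; the other settings were planned. Of 342 named gene results, RLE scaling and the replicate block changed no call, the GC and length correction ended 6 and gained 2, DESeq2 ended 2 of 335 (IL33 and MMP1), a model of the compared groups alone ended 67, and leaving out a replicate ended 93 of 1368. The model of the compared groups alone also gained 1 call, and leaving out replicates or libraries of steep GC trend gained a few. No gene called in the model of all groups changed sign, and no list was called in opposite directions. Counts were compared by size alone, so they could not reverse. Fits without the libraries of GC slope over 2 and 3 MAD ended 21 and 8 of the 342. Of 100 list results, an estimated correlation ended 19, fry added 24, and the GC and length correction ended 4 and added 2, alone and with the replicate block. RLE scaling and the stricter filter moved none of the 25 counts of genes by over 1.5 times. The planned scaling by spike-in RNA was not run, because the count table used holds no spike-in entries. Some settings use fewer libraries or fewer degrees of freedom, but why a call or count moved was not tested for any setting here. The shallowest library, replicate 1 of induced cells at 24 h with 1000 nM, had 2537678 counts and 14538 genes with at least 1 count, the fewest of the 96; how depth limits calls was not compared between groups.

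Lists called with an estimated correlation numbered 6 for 1000 nM in induced cells (13 as reported), 7 for induction at 24 h against 0 h (13) and 7 against uninduced cells (12); fry called 13 for 1000 nM in uninduced cells (6). With the GC and length correction, EGFR ligands (0.153), interferon response (0.0667) and keratinocyte markers (0.145) were lost for 1000 nM in induced cells and fibroblast markers (0.08) for induction at 24 h against 0 h, while glycolysis at 62.5 nM (0.0213) and retinal pigment epithelium genes at 1000 nM (0.0146) were gained in induced cells. Without the libraries of GC slope over 2 MAD the same 4 were lost (0.135, 0.052, 0.135 and 0.0671), and without those over 3 MAD EGFR ligands (0.136) and keratinocyte markers (0.111).

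A model of the compared groups alone called 2247 genes at 1000 nM and 1742 at 250 nM in induced cells, and 2978 at 250 nM, 9 at 62.5 nM, 2 at 15.6 nM and 0 at 3.9 nM in uninduced cells (edgeR; 15 in the model of all groups at 3.9 nM, and 6 by DESeq2). It called 140, 663 and 856 in the joint tests at 1, 4 and 8 h, 100, 860 and 4370 for induction at 1, 2 and 4 h, 97 for induction at 1000 nM and 1770 for the interaction. Its models of induction against 0 h hold 12 libraries at 0 h and 2 induced libraries. Their spread thus rests mostly on libraries that share 2 replicate numbers.

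The GC and length correction gave 1874 at 15.6 nM and 626 at 3.9 nM in induced cells, 43 at 15.6 nM in uninduced cells, 2065 and 2007 in the joint tests at 2 and 4 h, 593 for induction at 2 h and 1635 for induction at 1000 nM. With the replicate block as well, these were 2127, 831 and 82, then 2349 in the joint test at 4 h, 681 and 1850; the joint test at 1 h gave 135 and 62.5 nM in uninduced cells 1362. The replicate block alone moved 1 count by over 1.5 times, 15.6 nM in uninduced cells (26), and changed 5 of the 100 list calls, all given above. DESeq2 gave 30 at 15.6 nM and 6 at 3.9 nM in uninduced cells. Without the low-count filter there were 33 at 3.9 nM in uninduced cells, 542 in the joint test at 1 h and 4 for culture time.

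Without libraries of GC slope over 2 MAD, counts were 1457 at 15.6 nM and 645 at 3.9 nM in induced cells, 36 at 15.6 nM in uninduced cells, 196 in the joint test at 1 h, 2770 and 3378 for induction at 16 and 4 h and 588 for induction at 1000 nM; over 3 MAD, 433 at 3.9 nM in induced cells. Without the 62.5 nM dose the joint count at 2 h was 429. With the 0 h libraries summed, induction gave 177, 788, 2154, 2941 and 3000 at 2, 4, 8, 16 and 24 h.

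Leaving out 1 replicate gave, for induction at 1, 2, 4, 8, 16 and 24 h, 32 to 47, 166 to 341, 667 to 1694, 1938 to 4096, 2010 to 4713 and 2759 to 4143. Induction at 0 and 1000 nM gave 2023 to 2140 and 749 to 1171, and culture time 0 throughout by edgeR (322 at an unadjusted p under 0.05 with all libraries, 0 by DESeq2). At 3.9, 15.6, 62.5, 250 and 1000 nM, induced cells gave 63 to 165, 495 to 606, 1456 to 2005, 2166 to 3329 and 3832 to 4371, and uninduced cells 0 to 29, 2 to 4, 329 to 1326, 3148 to 4815 and 4784 to 5033. The joint tests at 1, 2, 4, 8 and 16 h gave 29 to 54, 401 to 642, 477 to 700, 1286 to 3027 and 2492 to 2635, and the interaction 2237 to 2248. Lists called were 11 to 13 and 12 for induction against 0 h and uninduced cells, 6 for 1000 nM in uninduced cells, and 11 to 12 and 8 to 13 for 62.5 and 1000 nM in induced cells.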

Other observations

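The GC and length correction, the joint test without 62.5 nM and the tests of a stronger response at 2 h and of growth arrest were chosen after the data were seen, and the genes and lists in the opening paragraphs were picked after their values were seen.

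Part of the interferon list fell within hours of induction and rose with the inhibitor in induced cells. IFIT1, an antiviral RNA-binding protein, was at 10.4 ± 1.73 CPM at 0 h (SD, n = 12) and 2.8 ± 0.429 CPM 4 h after induction (n = 2), a log2 fold change of -1.88 ± 0.26 (SE; edgeR adjusted p = 5.47e-08), and at -2.22 ± 0.3 at 8 h (edgeR adjusted p = 1.82e-08). IFIT2, its neighbour and relative, was at -1.26 at 2 h and -2.42 at 8 h (edgeR adjusted p = 0.000434 and 2.1e-08). With 1000 nM inhibitor in induced cells, IFIT1 was higher than without it by 2.05 ± 0.3 at 4 h and 3.17 ± 0.33 at 8 h, and IFIT2 by 1.69 and 2.9. The list of 14 had 7 lower at 8 h of induction (7 adjusted over the list alone, median -0.38, camera adjusted p = 0.0134, held with an estimated correlation). With 1000 nM, 6 rose at 8 h (6 over the list alone, median 0.42, camera adjusted p = 0.000654, held with an estimated correlation). At 24 h of induction the list was not called (3 higher and 6 lower, the same over the list alone, camera adjusted p = 0.273), nor with 1000 nM in uninduced cells (5 higher and 2 lower, the same over the list alone, camera adjusted p = 0.394). Its call with 1000 nM in induced cells at 24 h (camera adjusted p = 0.0455) was lost with an estimated correlation (0.064), the replicate block (0.0554) and the GC and length correction (0.0667), without the libraries of GC slope over 2 MAD (0.052), and without replicate 2 of 1000 nM (0.13) or of 0 nM (0.0661).

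Part of the ribosome biogenesis list was higher at 8 h of induction, and part was lower at 24 h. MYC, a transcription factor that drives ribosome production, was above 0 h by 0.58 at 1 h and 0.63 at 4 h, and below it at 24 h (-0.72, edgeR adjusted p = 3.33e-06). RRS1, a ribosome assembly factor, was higher by 0.65 ± 0.12 at 4 h and 0.89 ± 0.12 at 8 h (edgeR adjusted p = 7.32e-05 and 4.77e-08) and at -0.06 at 24 h. NOP56 was at 0.38 ± 0.08 at 8 h and -0.52 ± 0.09 at 24 h (edgeR adjusted p = 0.000213 and 2.15e-06). Of the list of 20, 9 were higher and 1 lower at 8 h (10 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.0157; adjusted p = 0.331 with an estimated correlation), and 9 were lower at 24 h (10 over the list alone, median -0.28, camera adjusted p = 0.00266; adjusted p = 0.22 with an estimated correlation). With 1000 nM inhibitor MYC was lower at 1 h (-2.18 ± 0.16, edgeR adjusted p = 6.67e-17), and 16 of the 20 ribosome genes were lower at 8 h (17 over the list alone, median -0.57, camera adjusted p = 1.65e-07), held with an estimated correlation.

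The joint inhibitor count was 2.46 times as high at 2 h as at 4 h. Over the other 4 doses the ratio was 0.301 (429 genes against 1423), which is consistent with the libraries of a single dose, 62.5 nM, as the source. A stronger response to the inhibitor at 2 h is argued against by the ratio at 1000 nM, 0.324. With the GC and length correction the ratio was 1.03, so whether a GC or length trend explains the whole excess cannot be told apart from another property of those libraries. At 2 h the 62.5 nM libraries also held the lowest BRAF levels (365.6 and 319.5 CPM, against 622.4 ± 22.34 CPM at 0 nM and 584.6 ± 15.06 CPM at 1000 nM, SD, n = 2 each). Small nuclear, nucleolar and Cajal body, miscellaneous and mitochondrial ribosomal RNAs together made up 0.211% and 0.216% of their counts. The median of that share was 0.134% over 96 libraries, and it was 0.215% and 0.143% at 0 nM.

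Sterol synthesis transcripts were higher with 1000 nM in induced cells by a median of 2.31. Without the shallow library, replicate 1 of that group, the median was 2.25, and with the GC and length correction and the replicate block it was 2.34, with the list past camera in both, which argues against depth and against a GC or length trend as the whole cause. In induced cells the same list was already higher with 1000 nM at 2 h (mean log2 CPM 6.437 and 6.412, against 6.191 and 6.238 at 0 nM). The rise was larger from 4 h on, and the list also rose at 62.5 nM in uninduced cells. Its interaction had medians of -0.15, -0.32, -0.34, -0.01 and 0.43 at 3.9, 15.6, 62.5, 250 and 1000 nM, past camera at 15.6 nM (camera adjusted p = 0.00034) and 62.5 nM (0.00359), both held with an estimated correlation. Growth arrest as the whole cause is argued against by 250 nM in induced cells, where the list rose by a median of 1.62 while the mean of the replication and mitosis members rose by 0.48 (replicates 0.54 and 0.43). With a single inhibitor, ERK activity cannot be separated from other effects of the compound, and culture density was not tested.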
